A study of Mus musculus with 3 samples.

How the data were processed

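Cells of 3 tumours of 1 mouse strain had been sorted as negative for CD45, CD31 and PDGFRa and sequenced with 10x 3' v2 chemistry, per the labels' protocols. The submitters' processing notes list Cell Ranger 2.1.1 and Seurat 3.0; the role of each, the genome build and the annotation are not given in the sources used here. The authors deposited 1 matrix of UMI counts for all tumours, in whole numbers and not normalized, with a list of cell barcodes and a list of gene symbols paired with gene identifiers. The suffix of each barcode gives its tumour, per the labels. Whether reads were downsampled when the libraries were joined is not given in the sources used here. The authors also deposited a table of clusters with a log2 fold change and an adjusted p-value per gene and cluster, per the file headers; its test and its clustering are not given in the sources used here, its values rest on cells pooled over tumours, and it was copied without a test.

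The matrix held 28692 genes, of which 21005 had counts, and the 67 entries that repeat a symbol were kept as genes of their own by identifier. Depth ranged from 3276 to 63149 UMIs per barcode in tumour 1, 3327 to 68873 in tumour 2 and 2147 to 42862 in tumour 3, so shares of cells with a UMI are also given after thinning each cell to 3000 UMIs. The tumours shared 50, 65 and 57 barcode sequences in pairs, out of 5874 to 7615 barcodes each. Barcodes with fewer than 500 genes (11, 0 and 16 in tumours 1, 2 and 3) or over 20% mitochondrial counts (61, 15 and 171) were left out. Scrublet scores were computed per tumour, as provided by scanpy. Its automatic threshold of 0.569 marked 0.016% of tumour 2, which is too few for a working caller, so after the scores had been seen the mean of the thresholds of tumours 1 and 3 (0.254 and 0.276), 0.265, was used there. It removed 68, 93 and 178 cells (1.17%, 1.53% and 2.40%).

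The 18963 kept cells were scaled to 10000 counts, log-transformed and clustered together (30 principal components, 15 neighbours, Leiden resolution 1, genes in at least 10 cells). Clustering used 2093 genes: 2000 variable genes from even-numbered lines of the gene list, without the genes of the fixed lists, and the cell type markers. These genes, markers included, were left out of the tests between classes, so Ptprc, Pecam1 and Pdgfra are given as levels only. The 31 clusters were named from 14 lists with 110 markers. A marker was raised in a cluster when seen in at least 20% of its cells and at least 2-fold higher than in the other cells. A class other than epithelial or fibroblast named a cluster with at least 3 and at least 50% of its markers raised. Of the rest, a cluster was called epithelial-like with at least 70% of the epithelial markers seen in 20% of its cells and more of them than of fibroblast markers, and otherwise fibroblast-like with at least 5 fibroblast markers raised. A name was dropped where the 10 leading genes held more markers of another class than of its own. The markers, the gene lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined, while this rule for naming clusters was set after the clusters had been seen. It left 7 clusters unnamed.

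Counts were summed per tumour and class, giving 6 sums per comparison, with 5026905 to 38567995 UMIs for the epithelial- and fibroblast-like sums and 876118 or more for the pericyte- or smooth muscle-like sums. Each comparison was fitted with edgeR's quasi-likelihood test (TMM normalization, filterByExpr, Benjamini-Hochberg at 0.05) with the tumour as a block, since both sums of a pair come from the same tumour. The classes compared with epithelial-like cells were the largest others by their smallest number of cells in any tumour, with at least 20 cells in each. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. The median log2 fold change of all tested genes was 0.09 against fibroblast-like and 0.14 against pericyte- or smooth muscle-like cells. For the Msi2 comparison, epithelial-like cells with at least 3000 UMIs were thinned to that number and summed by whether a Msi2 UMI was left, and Msi2 was left out. Gene lists were tested with camera at a preset correlation of 0.01 and again with a correlation estimated per list, for lists with at least 5 tested members, with Benjamini-Hochberg adjustment over the lists of a comparison.

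The 25 lists cover stem cell and progenitor genes, nuclear receptors, cytokines with chemokines and growth factors, cytokine receptors and checkpoint ligands, epithelial-mesenchymal transition, classical and basal-like pancreatic tumour types, S phase, G2 and M phase, p53 targets, p53 and RB regulators, hypoxia and glycolysis, interferon response, MHC class I, MHC class II, immediate early and heat shock genes, fibrillar matrix, basement membrane, inflammatory fibroblasts, myofibroblasts, the Wnt, Notch and Hedgehog pathways, tuft cells, and lipid and cholesterol metabolism. The named genes of a comparison are the 12 highest and 12 lowest log2 fold changes among genes past the threshold with 1 sign in all 3 tumours and an average log2 CPM of at least 5, without unnamed gene models, then up to 4 members past the threshold per list with the largest change, and Msi2, Prom1, Cd44, Il10rb, Il34, Csf1r, Trp53, Cdkn2a, Cdkn1a and the sort antigens. Genes outside this rule (Shh, Ihh, Phlda3, Ccng1, the genes of the unnamed clusters and those of the deposited table) were chosen after their values were seen. Some genes that the rule takes are not reported here. Between tumours, where no test was made, the 10 genes with the largest ratio of highest to lowest tumour and at least 50 CPM in the highest are given. Shares have exact binomial (Clopper-Pearson) 95% intervals, and a count of 0 allows up to 3 counts.

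The tests were tested on simulated data with 200 changed genes. Of the genes changed 2-fold and 4-fold, 60% and 97% were recovered for the 12091 genes of the fibroblast-like comparison, 49% and 82% for the 11521 of the pericyte- or smooth muscle-like one, 80% and 99% for the 11032 of the Msi2 one, and 47% and 92% for the 10082 of the mesothelial-like one. False calls were 9.25%, 4.38%, 2.19% and 8.55% of the calls in 1 simulated data set per comparison. The fibroblast-like and mesothelial-like values lay above the nominal rate. The real comparisons between classes called far more than 200 genes, so these rates may not hold for them. Alternatives to the fit were DESeq2's size factors or its Wald test, no filter on low counts, no block, and each tumour left out. Alternatives to the clustering were variable genes from odd-numbered lines, Leiden resolution 0.5 and 2, and doublets kept. Other filters were at least 1000 genes per cell, at most 10% mitochondrial counts, and all barcodes except the Scrublet doublets. The last alternatives were equal cell numbers, thinning to 1500 or 6000 UMIs or none, and matched cluster makeup. The comparison of mesothelial-like with fibroblast-like cells was added after the data had been seen. Computation used Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.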

Results

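The data came from 3 pancreatic tumours of KPf/fC mice, a model in which Cre recombinase acting in the pancreas removes Trp53. Cells lacking CD45 (haematopoietic cells), CD31 (endothelial cells) and PDGFRa (many fibroblasts) at the surface had been sorted and profiled by 10x 3' v2 single-cell RNA sequencing, in which unique molecular identifiers (UMIs) count transcripts. The stated aim was a survey of transcription in single cells of these tumours. The 3 tumours form 1 group with no treatment or genotype contrast, so the comparisons are between cell classes within each tumour, with the tumour as replicate. The labels number the tumours as separate samples and do not say whether each came from its own animal. The p-values therefore rest on how far the differences between classes vary between these tumours. The matrix held 19576 barcodes, of which 5874, 6087 and 7615 belonged to tumours 1, 2 and 3. Total UMIs were 60801677, 67262634 and 53162622, and the median UMI count per barcode was 8460.5, 9052 and 6025. After filtering, 5734, 5979 and 7250 cells remained.

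Epithelial-like cells were the largest named class, with 53.6% of the kept cells of tumour 1, 34.9% of tumour 2 and 58.0% of tumour 3 (48.8% ± 12.3, SD, n = 3). Fibroblast-like cells followed at 22.1%, 11.6% and 25.9% (19.9% ± 7.41, SD, n = 3). Pericyte- or smooth muscle-like cells made up 3.64% ± 1.00 and mesothelial-like cells 3.67% ± 1.85 (SD, n = 3). Endothelial-like cells (1.78% ± 1.81), acinar-like cells (1.19% ± 0.97) and endocrine-like cells (0.12% ± 0.05) were scarce (SD, n = 3). No cluster took a macrophage, neutrophil, dendritic, T, B, Schwann or erythroid name. Unnamed clusters held 9.30% of tumour 1, 48.9% of tumour 2 and 4.48% of tumour 3, and most of those in tumour 2 came from 4 clusters with 43.8% of its cells (exact binomial 95% interval 42.6% to 45.1%). One unnamed cluster, with 1.94%, 1.69% and 2.47% of the cells of tumours 1, 2 and 3, carried pericyte markers and lost that name because the neutrophil marker Mmp9 was among its leading genes. The sort sets these shares, which therefore describe the sorted cells and not the tumours. Intervals of shares and limits from counts of 0 cover counting error only.

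**Figure D1:**
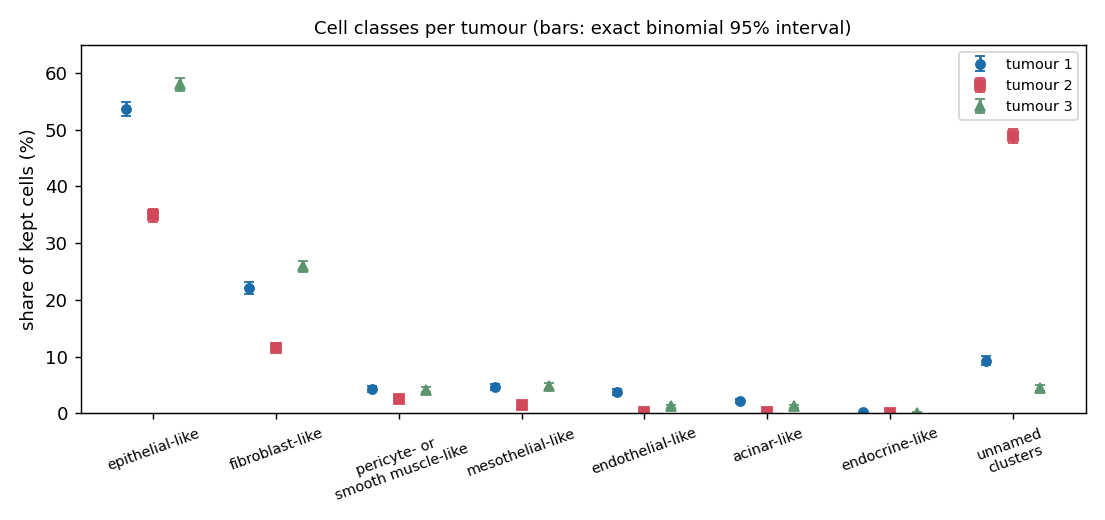
Share of kept cells (%, y axis) in each cell class (x axis) for tumours 1, 2 and 3, with exact binomial 95% intervals as bars. Epithelial-like cells lie at 53.6%, 34.9% and 58.0%, and unnamed clusters reach 48.9% in tumour 2 against 9.30% and 4.48% in the others.

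RNA for CD31 was concentrated in endothelial-like cells, RNA for PDGFRa was seen in several classes, and RNA for CD45 was rare in each. Ptprc, which encodes CD45, had a UMI in 0.358%, 0.575% and 0.832% of epithelial-like cells and in 0%, 0% and 0.160% of fibroblast-like cells of tumours 1, 2 and 3, where a count of 0 allows up to 0.237% and 0.433% in tumours 1 and 2. Pecam1, which encodes CD31, had a UMI in 95% of the endothelial-like cells of tumour 1 and 82.0% of those of tumour 3, against 2.02% and 1.02% of epithelial-like cells. Pdgfra had a UMI in 55.0%, 40.7% and 45.3% of fibroblast-like cells, against 1.85%, 1.25% and 1.28% of epithelial-like cells, and averaged 114 ± 23.3 against 1.60 ± 0.112 CPM (counts scaled to equal depth; SD, n = 3). It was also seen in 18.9%, 18.5% and 42.2% of mesothelial-like cells and in 40.5%, 22.8% and 10.8% of cells of unnamed clusters. Median depth was 10982.5, 8468.5 and 7278 UMIs in epithelial-like cells, 6499, 6873 and 4697.5 in fibroblast-like cells, and 4885.5 and 2964 in the endothelial-like cells of tumours 1 and 3. With each cell thinned to 3000 UMIs, Pecam1 was seen in 83.9% and 68.2% of the endothelial-like cells of tumours 1 and 3, against 0.455% and 0.377% of epithelial-like cells. Thinned, Pdgfra was seen in 32.5%, 22.2% and 31.0% of fibroblast-like against 0.39%, 0.192% and 0.377% of epithelial-like cells, and Ptprc in 0.163%, 0.144% and 0.377% of epithelial-like cells. The sort acted on surface protein, and these values are RNA.

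Msi2, an RNA-binding protein used as a stem cell marker in these tumours, was detected in each of the compared classes. Msi2 had a UMI in 50.7%, 49.8% and 49.8% of epithelial-like cells, 19.4%, 29.1% and 24.9% of fibroblast-like cells and 13.9%, 12.1% and 18.5% of pericyte- or smooth muscle-like cells. With each cell thinned to 3000 UMIs, the shares were 17.9%, 22.3% and 25.6% of epithelial-like, 8.76%, 13.6% and 16.8% of fibroblast-like and 9.02%, 6.71% and 16.6% of pericyte- or smooth muscle-like cells. Thinning left out 222 epithelial-like, 328 fibroblast-like and 139 pericyte- or smooth muscle-like cells, all of tumour 3.

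Epithelial-like cells were first compared with fibroblast-like cells, the largest other class, to find which of the genes not used for clustering differ between these classes. Whether the epithelial-like cells were tumour cells was not tested. The 12 highest genes included members of the classical pancreatic tumour list, the tight junction gene Cldn18 (log2 fold change 5.99 ± 0.26, SE, n = 3), the trefoil factor Tff1 (5.27 ± 0.15), the mucin-folding disulfide isomerase Agr2 (5.42 ± 0.35) and the gastrokine Gkn2 (5.25 ± 0.19). The lowest were the matrix protein Abi3bp (-8.66 ± 0.19), the microfibril component Mfap5 (-7.45 ± 0.19), the chemokine Cxcl14 (-7.43 ± 0.20) and the Wnt antagonist Sfrp1 (-7.42 ± 0.17). Prom1, which encodes the stem cell antigen CD133, was 4.53 ± 0.22 higher. Msi2 was higher by 0.78 ± 0.14, with 66.5, 83.0 and 97.3 CPM in epithelial-like against 35.0, 50.1 and 60.5 CPM in fibroblast-like cells.

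By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 6186 of 12091 genes differed, 3351 higher and 2835 lower in epithelial-like cells. The genes named among the 12 highest and 12 lowest were chosen to have the same sign in 3 of 3 tumours. Each had an adjusted p of at most 1.22e-05 by that edgeR test. Other genes among the 12 highest were the lectin Lgals2 (5.91 ± 0.25), the raft protein Mal (5.39 ± 0.20), the EGF receptor ligand Areg (5.37 ± 0.19), Ly6d (5.19 ± 0.36), the tetraspanin Tspan8 (5.19 ± 0.17), Vsig2 (5.16 ± 0.23), Cmtm8 (5.14 ± 0.24) and the peptidoglycan recognition protein Pglyrp1 (5.11 ± 0.23). Other genes among the 12 lowest were the small leucine-rich proteoglycan Ogn (-7.39 ± 0.24), the fibrillin Fbn2 (-7.37 ± 0.24), Islr (-7.35 ± 0.19), the ephrin receptor Epha3 (-7.33 ± 0.21), the transcription factor Osr2 (-7.29 ± 0.21), C1qtnf7 (-7.24 ± 0.22), the growth factor Igf1 (-7.18 ± 0.15) and the eosinophil chemokine Ccl11 (-7.18 ± 0.21). Msi2, Prom1, the hyaluronan receptor Cd44 (2.17 ± 0.13) and Il10rb, a subunit of the interleukin-10 receptor (0.68 ± 0.16), were each higher in 3 of 3 tumours, with adjusted p = 0.00192, 2.1e-06, 6.9e-06 and 0.00801 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The macrophage growth factor Il34 (-1.05 ± 0.23) and its receptor Csf1r (-2.18 ± 0.43) were lower in 3 of 3 tumours, with adjusted p = 0.00617 and 0.00338 by the same edgeR test and Benjamini-Hochberg adjustment. Csf1r was low in both classes, at 0.635 ± 0.378 CPM in epithelial-like and 3.21 ± 2.31 CPM in fibroblast-like cells (SD, n = 3). Epithelial markers reached a median of 4.10%, 2.68% and 3.45% of their epithelial-like level in the fibroblast-like sums of tumours 1, 2 and 3.

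**Figure D2:**
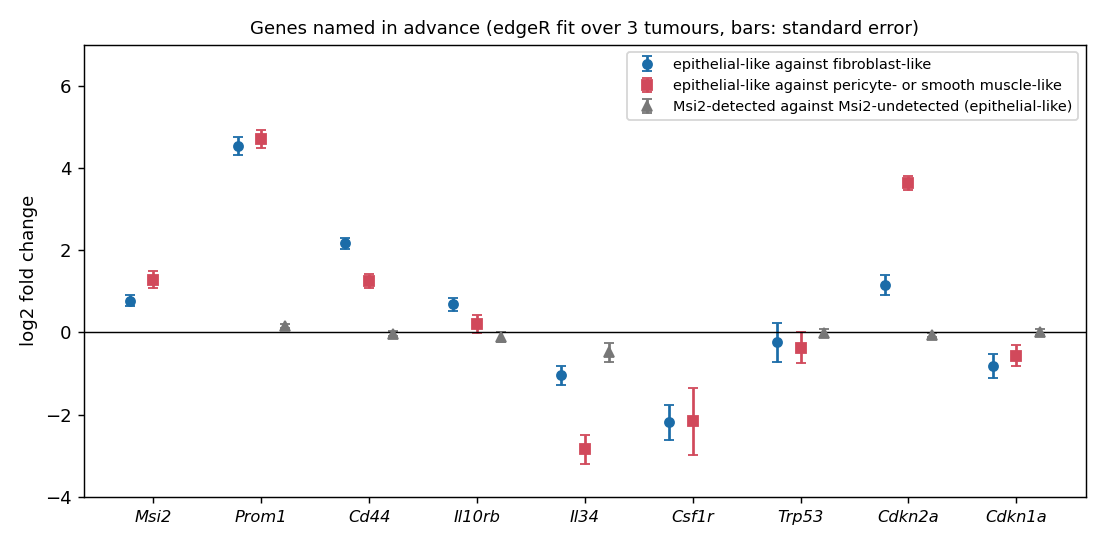
Log2 fold change ± SE (y axis, 3 tumours) of 9 genes chosen in advance (x axis) in 3 comparisons: epithelial-like against fibroblast-like, epithelial-like against pericyte- or smooth muscle-like, and Msi2-detected against Msi2-undetected epithelial-like cells. Prom1 lies at 4.53 and 4.71 in the comparisons between classes and at 0.15 between Msi2-detected and Msi2-undetected cells.

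Of the 25 fixed gene lists, 11 passed camera's test with the preset correlation in this comparison, and 0 with an estimated correlation. Of the genes of the classical pancreatic tumour type, 18 of 19 were higher and none lower, with Tff1, Agr2, Cldn18 and Gkn2 as the largest (median log2 fold change 5.04; camera, adjusted p = 1.8e-09, and adjusted p = 0.416 with an estimated correlation). All 22 fibrillar matrix and matrix remodelling genes were lower (median -5.68, adjusted p = 2.7e-15, and adjusted p = 0.231 with an estimated correlation), such as collagen Col5a2 (-6.50 ± 0.16), Thbs2 (-6.38 ± 0.16), biglycan Bgn (-6.30 ± 0.19) and the matrix protease Mmp2 (-6.30 ± 0.14). Of the epithelial-mesenchymal transition genes 17 of 18 were lower, among them cadherin 11 (Cdh11, -6.93 ± 0.17), Sparc (-6.68 ± 0.15) and the transcription factor Prrx1 (-6.53 ± 0.33). Their median was -3.81 (camera, adjusted p = 3.7e-09, and adjusted p = 0.231 with an estimated correlation). Of the myofibroblastic genes 11 of 12 were lower (median -4.65, adjusted p = 1.5e-07, and adjusted p = 0.231 with an estimated correlation), with Col15a1 at -6.65 ± 0.22 and the actin-binding Tagln at -6.52 ± 0.26. Of the inflammatory fibroblast genes 14 of 15 were lower, including the cytokine Il6 (-6.10 ± 0.22), Pi16 (-6.98 ± 0.17) and Clec3b (-7.15 ± 0.24). Their median was -3.15 (camera, adjusted p = 1.2e-06, and adjusted p = 0.416 with an estimated correlation).

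Of the G2 and M phase genes 20 of 22 were higher, with the kinesin Kif23 at 2.61 ± 0.31 and the ubiquitin-conjugating enzyme Ube2c at 2.24 ± 0.17. Their median was 1.25 (camera, adjusted p = 8.2e-06, and adjusted p = 0.478 with an estimated correlation). Of the S phase genes 13 of 21 were higher and 2 lower, with the helicase genes Hells at 1.89 ± 0.27 and Mcm2 at 1.84 ± 0.26. Their median was 0.82 (camera, adjusted p = 0.0144, and adjusted p = 0.582 with an estimated correlation). Interferon response genes were lower in 14 of 19 cases, including Ifit2 (-3.89 ± 0.56), Zbp1 (-3.06 ± 0.23) and Ifit3 (-2.83 ± 0.36). Their median was -1.73 (camera, adjusted p = 9.0e-06, and adjusted p = 0.416 with an estimated correlation). Of the MHC class I genes, which act in antigen presentation, 7 of 11 were lower, such as the peptide transporter Tap2 (-2.56 ± 0.25) and B2m (-1.44 ± 0.13). Their median was -1.24 (camera, adjusted p = 0.00112, and adjusted p = 0.478 with an estimated correlation). Cytokine receptors and checkpoint ligands were lower in 16 and higher in 5 of 32 cases, with Tgfbr2 at -3.43 ± 0.18, Il1r1 at -3.44 ± 0.27 and Il18r1 at 3.50 ± 0.31. Their median was -0.73 (camera, adjusted p = 0.00645, and adjusted p = 0.416 with an estimated correlation). In the Hedgehog list the responding genes Gli1 (-5.88 ± 0.29) and Gli2 (-6.04 ± 0.30) were lower while the ligands Shh (4.03 ± 0.42) and Ihh (4.46 ± 0.61) were higher, 6 lower and 2 higher of 9. Their median was -2.77 (camera, adjusted p = 0.0272, and adjusted p = 0.416 with an estimated correlation).

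The other 14 lists did not pass the test by camera with Benjamini-Hochberg adjustment, although many of their members did by edgeR. Stem cell and progenitor genes were higher in 9 and lower in 4 of 17 cases (median 0.78, adjusted p = 0.123), with Cd24a at 4.71 ± 0.15, the hepatocyte growth factor receptor Met at 3.88 ± 0.23 and the chromatin protein Hmga2 at 3.83 ± 0.35. Nuclear receptors split into 7 higher and 10 lower of 22 (median -0.29, mean 0.22, adjusted p = 0.466), from the oestrogen receptor Esr1 at -6.05 ± 0.36 to the epithelial regulator Hnf4a at 5.40 ± 0.39. Cytokines, chemokines and growth factors gave 13 higher and 18 lower of 35 (median -1.05, adjusted p = 0.170), with Hgf at -7.20 ± 0.42. Basal-like genes gave 5 higher and 1 lower of 8 (median 3.34, adjusted p = 0.125), with Krt17 at 4.09 ± 0.35 and Fam83a at -5.01 ± 0.32. Regulators of the p53 and RB pathways gave 6 higher and 1 lower of 10 (median 0.43, adjusted p = 0.272), with cyclin D1 (Ccnd1) at 3.38 ± 0.13 and Cdkn2a at 1.16 ± 0.25. Basement membrane genes gave 6 higher and 8 lower of 14 (median -1.70, adjusted p = 0.438), the laminins Lama3 (4.92 ± 0.28) and Lamb3 (4.16 ± 0.18) among the higher and Lama4 (-4.34 ± 0.29) and Nid1 (-4.33 ± 0.26) among the lower. Wnt pathway genes gave 10 higher and 9 lower of 23 (median -0.20, adjusted p = 0.612), with Wnt7a at 4.44 ± 0.31 and Nkd1 at -5.77 ± 0.24. Notch pathway genes gave 7 higher and 2 lower of 12 (median 0.96, adjusted p = 0.215), and lipid and cholesterol genes 9 higher and 4 lower of 16 (median 0.81, adjusted p = 0.341). Hypoxia and glycolysis genes (8 higher and 3 lower of 18, median 0.47, adjusted p = 0.633), immediate early and heat shock genes (4 and 6 of 18, median 0.08 with the test pointing down, adjusted p = 0.998), MHC class II genes (1 and 2 of 6, median -0.46, adjusted p = 0.357) and tuft cell genes (2 and 3 of 7, median -0.19, mean 0.12, adjusted p = 0.835) were mixed. Adjusted over the list alone, the counts were the same except for 8 higher nuclear receptors, 18 lower cytokine receptors, 21 higher G2 and M phase genes, 9 higher hypoxia genes, 15 lower interferon genes, 12 lower myofibroblastic genes, 3 lower Notch genes and 10 higher lipid genes. Without the tumour as a block, 3895 genes passed edgeR's test, and with Scrublet doublets kept the MHC class II invariant chain Cd74 went from 1.86 to -0.54.

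**Figure D3:**
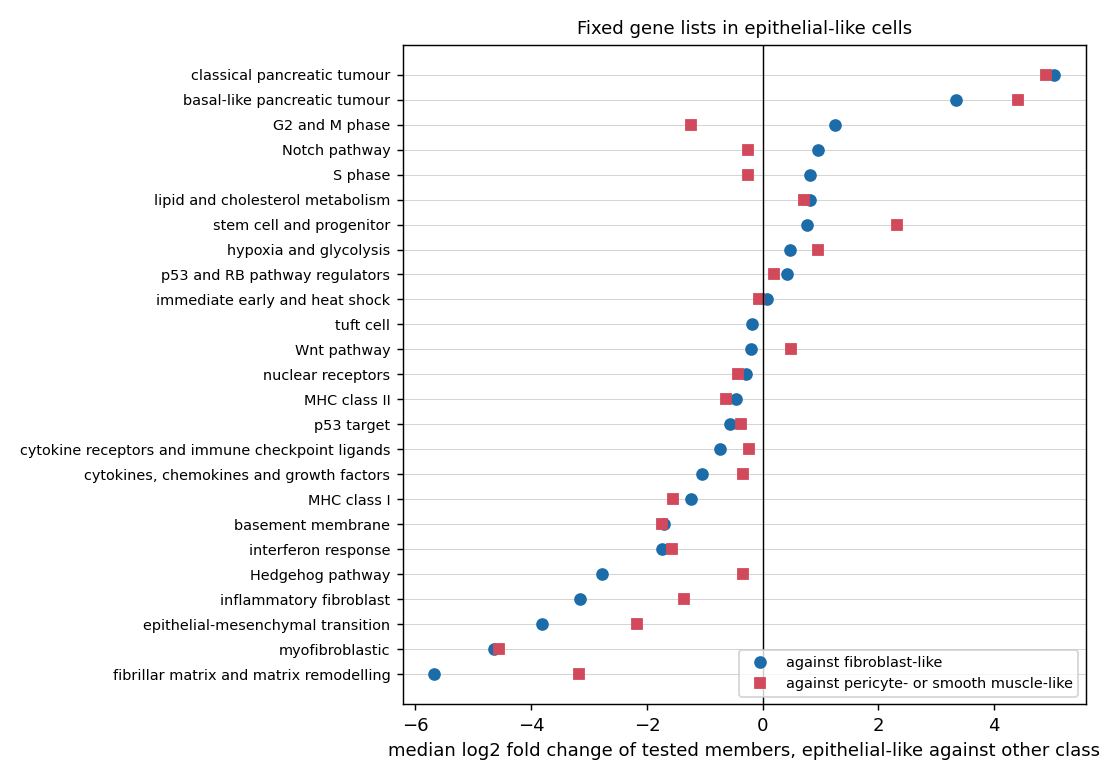
Median log2 fold change (x axis) of the tested members of each fixed gene list (y axis) in epithelial-like cells against fibroblast-like cells (circles) and against pericyte- or smooth muscle-like cells (squares). Classical tumour genes lie at 5.04 and 4.89 and fibrillar matrix genes at -5.68 and -3.17, while G2 and M phase genes lie at 1.25 and -1.23.

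Epithelial-like cells were next compared with pericyte- or smooth muscle-like cells, the class of the vessel wall. The 12 highest genes included the surfactant protein Sftpd (log2 fold change 6.39 ± 0.37, SE, n = 3), Agr2 (6.07 ± 0.23), the trefoil factor Tff2 (5.99 ± 0.20) and the mucin glycosyltransferase Gcnt3 (5.62 ± 0.38), together with the mast cell protease genes Mcpt1 (6.21 ± 0.43), Mcpt2 (5.76 ± 0.34) and Mcpt8 (5.69 ± 0.26). The 12 lowest included the endothelin receptor Ednrb (-9.13 ± 0.23), leiomodin Lmod1 (-8.89 ± 0.27), the smooth muscle actin Actg2 (-8.02 ± 0.28), the phosphodiesterase Pde3a (-8.21 ± 0.22) and the Notch target Heyl (-8.08 ± 0.26). Prom1 (4.71 ± 0.22) and Msi2 (1.28 ± 0.21) were higher than in this class too. The tumour suppressors of the Cdkn2 locus were much higher in epithelial-like cells, Cdkn2a by 3.64 ± 0.18 (495, 869 and 777 against 38.7, 102 and 53.6 CPM) and Cdkn2b by 3.79 ± 0.21.

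By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4759 of 11521 genes differed, 2824 higher and 1935 lower. The 12 highest and 12 lowest genes were chosen to have the same sign in 3 of 3 tumours. Each had an adjusted p of at most 7.5e-10 by that edgeR test. The rest of the highest were Tm4sf20 (6.25 ± 0.43), Lgals2 (6.0 ± 0.38), Palmd (5.95 ± 0.36), Sptssb (5.90 ± 0.43) and the ubiquitin ligase Cblc (5.70 ± 0.37). The rest of the lowest were the antitrypsin gene Serpina1d (-9.78 ± 0.35), whose near-identical neighbours could share its reads, asporin Aspn (-8.91 ± 0.24), Apold1 (-8.84 ± 0.27), Ndufa4l2 (-8.34 ± 0.23), Rasgrp2 (-8.20 ± 0.22), Ccl11 (-7.89 ± 0.22) and the guanylate cyclase Gucy1a3 (-7.79 ± 0.36). Adjusted p was 5.2e-05 for Msi2, 5.9e-13 for Prom1, 7.4e-06 for Cd44 (1.25 ± 0.17) and 1.3e-12 for Cdkn2a by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, each higher in 3 of 3 tumours. Il34 (-2.84 ± 0.36) and Csf1r (-2.16 ± 0.82) were lower in 3 of 3 tumours, with adjusted p = 2.1e-06 and 0.0409 by the same edgeR test and Benjamini-Hochberg adjustment. Csf1r was low here too, at 3.06 ± 2.12 CPM in pericyte- or smooth muscle-like cells (SD, n = 3). Il10rb was at 0.22 ± 0.22 (adjusted p = 0.461, edgeR, Benjamini-Hochberg). Some list genes had 0 counts in all pericyte- or smooth muscle-like sums, so only lower bounds can be given, taken at 3 counts over the group: the cytokine Csf2 was at least 30.4-fold higher, the chemokine Ccl20 6.87-fold, Wnt10a 5.82-fold, Shh 5.57-fold and Lemd1 3.40-fold.

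Classical tumour genes were higher in 18 of 18 cases (median 4.89; camera, adjusted p = 9.9e-10, and adjusted p = 0.209 with an estimated correlation). Basal-like genes were higher in 5 of 6 cases, with Krt17 at 4.91 ± 0.79 and Areg at 4.10 ± 0.28, and their median was 4.42 as fitted and 3.44 with Lemd1 at its bound (adjusted p = 0.00685, and adjusted p = 0.377 with an estimated correlation). Stem cell and progenitor genes were higher in 12 and lower in 2 of 16 cases, with Cd24a at 4.99 ± 0.20, Met at 4.84 ± 0.50 and the aldehyde dehydrogenase Aldh1a3 at 4.80 ± 0.32. Their median was 2.32 (camera, adjusted p = 0.00847, and adjusted p = 0.427 with an estimated correlation). Hypoxia and glycolysis genes were higher in 12 and lower in 2 of 18 cases, including Vegfa (3.45 ± 0.26), carbonic anhydrase Car9 (3.38 ± 0.40) and hexokinase Hk2 (2.79 ± 0.23). Their median was 0.95 (camera, adjusted p = 0.0472, and adjusted p = 0.577 with an estimated correlation). Lipid and cholesterol genes were higher in 9 and lower in 1 of 16 cases, with the sterol enzymes Sqle at 2.18 ± 0.26 and Fdft1 at 1.97 ± 0.25. Their median was 0.72 (camera, adjusted p = 0.0472, and adjusted p = 0.468 with an estimated correlation).

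Lower lists were the fibrillar matrix (18 of 22; Col6a3 -6.98 ± 0.19, Postn -6.74 ± 0.19; median -3.17, camera adjusted p = 1.8e-11, and adjusted p = 0.209 with an estimated correlation) and epithelial-mesenchymal transition genes (14 of 17; median -2.18, adjusted p = 4.3e-09, and adjusted p = 0.209 with an estimated correlation). Myofibroblastic genes were lower in 10 of 12 cases, with the contractile genes Tagln at -7.54 ± 0.18 and Myl9 at -7.54 ± 0.20. Their median was -4.55 (camera, adjusted p = 4.6e-08, and adjusted p = 0.212 with an estimated correlation). G2 and M phase genes were lower in 17 of 22 cases in this comparison, with Hmmr at -2.03 ± 0.29 and Cdk1 at -1.58 ± 0.20. Their median was -1.23 (camera, adjusted p = 6.3e-05, and adjusted p = 0.533 with an estimated correlation). The pericyte- or smooth muscle-like class included a cluster of 39 cells led by cell cycle genes such as Top2a and Cenpf. Interferon response genes were lower in 9 of 16 cases (median -1.56, adjusted p = 6.3e-05, and adjusted p = 0.317 with an estimated correlation), with Oasl2 at -3.39 ± 0.32 and Isg15 at -2.82 ± 0.35. MHC class I genes were lower in 8 and higher in 1 of 11 cases. Their median was -1.54 (camera, adjusted p = 0.00292, and adjusted p = 0.317 with an estimated correlation). Basement membrane genes were lower in 9 and higher in 5 of 14 cases, with the collagen chains Col4a1 at -5.44 ± 0.15 and Col4a2 at -5.28 ± 0.16 and the laminin Lama3 at 5.64 ± 0.42. Their median was -1.74 (camera, adjusted p = 0.00847, and adjusted p = 0.317 with an estimated correlation). Inflammatory fibroblast genes were lower in 7 and higher in 3 of 13 cases, with Il6 at -7.10 ± 0.22 and Ccl2 at -3.75 ± 0.20. Their median was -1.36 (camera, adjusted p = 0.00685, and adjusted p = 0.317 with an estimated correlation).

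The remaining lists did not pass camera's test against pericyte- or smooth muscle-like cells, with medians from -0.63 for MHC class II genes (adjusted p = 0.433) to 0.49 for the Wnt pathway (adjusted p = 0.259), and too few tuft cell genes were counted to test that list. Median and mean differed in sign for cytokines, chemokines and growth factors (-0.34 and 0.62) and p53 targets (-0.37 and 0.11). With the genes of 0 counts at their bounds, the mean of the cytokine list was 0.22. The Hedgehog list had a mean of 0.18 as fitted and -0.68 with Shh at its bound, beside a median of -0.33. Adjusted over the list alone, the counts were the same except for 6 higher nuclear receptors, 14 lower cytokines, 17 lower epithelial-mesenchymal transition genes, 4 lower S phase genes, 15 higher hypoxia genes, 11 lower interferon genes, 8 lower immediate early genes and 20 lower fibrillar matrix genes. Without the tumour as a block, 3010 genes passed edgeR's test, and Csf1r lost its call without tumour 2 at a like fold (-2.21, adjusted p = 0.0756, edgeR with Benjamini-Hochberg adjustment) and without tumour 3 at a smaller one (-0.97, adjusted p = 0.480), and was at -3.16 without tumour 1 (adjusted p = 0.0172).

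**Figure D4:**
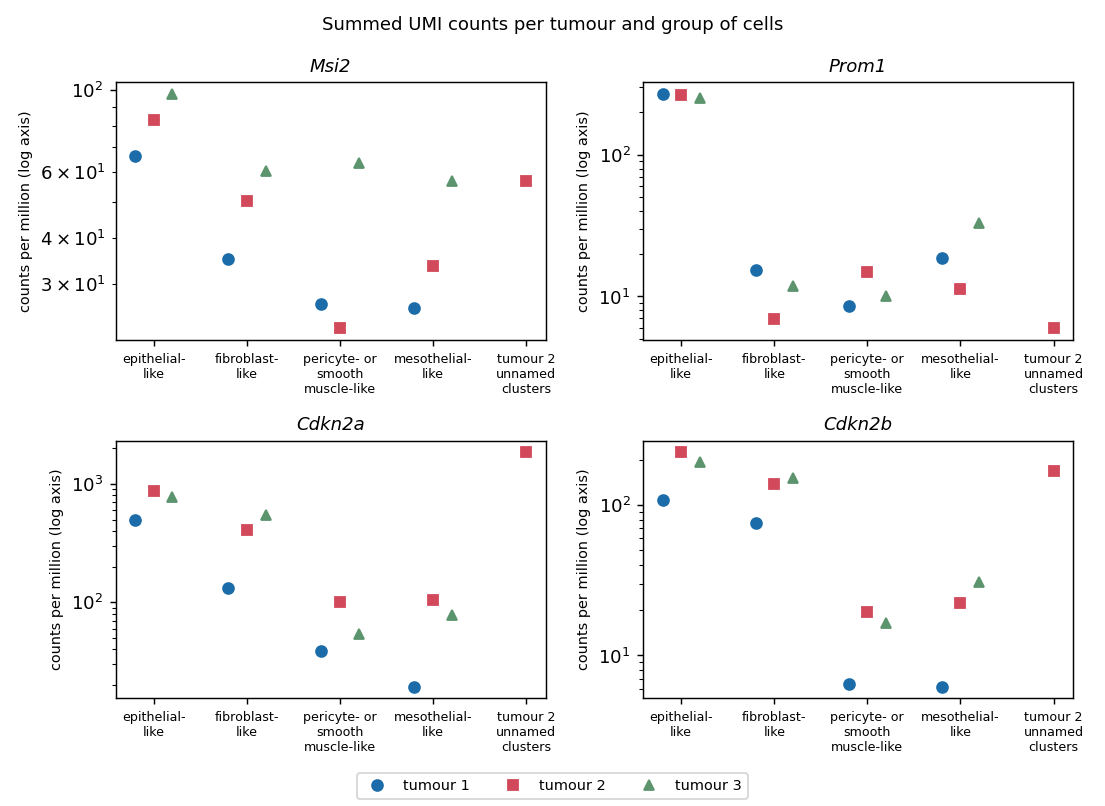
Level in CPM (y axis, log scale) of Msi2, Prom1, Cdkn2a and Cdkn2b in epithelial-, fibroblast-, pericyte- or smooth muscle- and mesothelial-like cells and in the 4 unnamed clusters of tumour 2 (x axis), 1 symbol per tumour. Cdkn2a lies at 495, 869 and 777 CPM in epithelial-like cells, at 132, 411 and 549 CPM in fibroblast-like cells and at 38.7, 102 and 53.6 CPM in pericyte- or smooth muscle-like cells.

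In published work on these tumours Msi2 marks cells with stem cell properties, so epithelial-like cells with a Msi2 UMI were compared with those without, after thinning each cell to 3000 UMIs. Msi2-detected cells had more Lcn2, a secreted iron-siderophore binder (log2 fold change 0.32 ± 0.04, SE, n = 3), more of the neuron navigator Nav2 (0.60 ± 0.11), the scavenger receptor Scara3 (0.35 ± 0.08), transferrin Trf (0.31 ± 0.07) and the nuclear RNA Malat1 (0.19 ± 0.03). They had less Agr2 (-0.51 ± 0.08), Anxa10 (-0.54 ± 0.11) and Gkn3 (-0.31 ± 0.05) of the classical list, less of the mitotic activator Cdc20 (-0.91 ± 0.20), and less vimentin (Vim, -0.35 ± 0.07), Lgals1 (-0.35 ± 0.05) and tubulin Tuba1a (-0.44 ± 0.08). Prom1 (0.15 ± 0.05) and Cd44 (-0.03 ± 0.05) did not pass the test. A cell without a UMI can still express Msi2, so the groups are mixtures.

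Msi2 was detected in 584 of 3076, 467 of 2086 and 991 of 3983 cells of tumours 1, 2 and 3 (19%, 22.4% and 24.9%, from a random draw of UMIs separate from that of the shares per class). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 49 of 11032 genes differed, 12 higher and 37 lower in Msi2-detected cells, against 980 at an unadjusted p under 0.05. The highest and lowest genes were chosen to have the same sign in 3 of 3 tumours, so that sign is no result. Some were near 0 in a tumour, such as Trf at 0.012 in tumour 3 and Vim at -0.063 in tumour 2. Adjusted p was 3.1e-04 for Lcn2, 0.00863 for Nav2, 0.00113 for Malat1, 8.1e-04 for Agr2, 0.0135 for Vim and 0.0306 for Cdc20 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of the named genes with an average log2 CPM of at least 5, the largest decreases sat in few cells: Zg16 (-5.09 ± 0.19) had 95.6% of its UMIs in 3 cells, Lypd8 (-3.27 ± 0.30) 33.2%, and Tff3 (-1.89 ± 0.22) 44.9%. Spink4 (-1.53 ± 0.12), Rbp2 (-0.49 ± 0.11), Cyb5b (-0.41 ± 0.09) and the gastric mucin Muc6 (-0.39 ± 0.08) were also lower. Lypd8 and Spink4 were among the leading genes of cluster 29, an epithelial-like cluster of 53 cells. Trf, which was higher, was among those of cluster 21, an epithelial-like cluster of 388 cells, 84.5% of them from tumour 1. Adjusted p was 0.341 for Prom1 and 0.932 for Cd44 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of the lists, G2 and M phase genes were lower as a set (median -0.42, camera adjusted p = 1.7e-07, and adjusted p = 0.846 with an estimated correlation), with 1 of 20 members called and 6 called lower when adjusted over the list alone. S phase genes were lower as a set (median -0.16, camera adjusted p = 0.00242, and adjusted p = 0.846 with an estimated correlation), with 0 of 21 members called by edgeR, also when adjusted over the list alone. Of the classical genes 3 of 18 were lower, 5 when adjusted over the list alone, with a median of -0.14 (camera, adjusted p = 0.163). The stem cell and progenitor list, without Msi2, had a median of -0.01 over 15 genes with 0 called (camera, adjusted p = 0.936). The other lists had adjusted p of at least 0.163 for nuclear receptors and up to 0.936. The count of genes was 17 with DESeq2, 0 without the tumour as a block, 4 without tumour 3 and 5 with Msi2-undetected cells drawn to match the clusters of the Msi2-detected cells. Without thinning, Lcn2 turned to -0.28 and Vim to 0.11.

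The strain carries a floxed Trp53 allele recombined in pancreatic cells, so p53 target genes were compared between epithelial-like cells and the other classes. Against fibroblast-like cells, 12 of 20 p53 targets were lower and 5 higher, among them the receptor Eda2r (-5.33 ± 0.40), the zinc finger gene Zmat3 (-2.46 ± 0.20), Phlda3 (-1.93 ± 0.13) and cyclin G1 (Ccng1, -1.33 ± 0.21) on the lower side and the desmosomal Perp (4.95 ± 0.24) and the BH3-only gene Pmaip1 (2.39 ± 0.26) on the higher side. Perp is also a gene of stratified epithelia. The median of the list was -0.56 (camera p = 0.0333, adjusted p = 0.0693 over the 25 lists, and adjusted p = 0.614 with an estimated correlation), and without tumour 2 it was -0.46 (camera p = 0.0976). Cdkn1a, the p53 target that encodes p21, was -0.82 ± 0.29 (adjusted p = 0.0446, edgeR's quasi-likelihood test, Benjamini-Hochberg), lower in 3 of 3 tumours, and -0.35 without tumour 2 (adjusted p = 0.164, edgeR). Against pericyte- or smooth muscle-like cells, 6 of 19 targets were lower and 3 higher (median -0.37, camera adjusted p = 0.179), and the median was -0.31, -0.28 and -0.18 without tumours 1, 2 and 3. Cdkn1a was at -0.56 ± 0.24 (adjusted p = 0.0735, edgeR's quasi-likelihood test, Benjamini-Hochberg). Without 1 tumour, Cdkn1a in this comparison was -0.82 (without tumour 1, adjusted p = 0.00105), -0.90 (without tumour 2, adjusted p = 0.00221) and 0.059 (without tumour 3, adjusted p = 0.821) by the same edgeR test with Benjamini-Hochberg adjustment. Trp53 itself was at -0.24 ± 0.48 and -0.37 ± 0.37 in the comparisons (adjusted p = 0.703 and 0.458, edgeR's quasi-likelihood test, Benjamini-Hochberg), with 38.0, 24.2 and 78.9 CPM in epithelial-like and 65.7, 61.7 and 27.4 CPM in fibroblast-like cells. Tumour 3 differed in sign from tumours 1 and 2, and without it the log2 fold change was -1.05 against fibroblast-like cells (adjusted p = 0.00217, edgeR with Benjamini-Hochberg adjustment) and -1.20 against pericyte- or smooth muscle-like cells (adjusted p = 7.71e-10). Tags at the 3' end can lie outside the removed exons, so these Trp53 values do not check the deletion. The p53 target list was also lower in mesothelial-like than in fibroblast-like cells, with 8 of 20 targets lower and 3 higher. Its median there was -0.43 (camera, adjusted p = 0.0347, and adjusted p = 0.636 with an estimated correlation). A median of p53 targets below that of fibroblast-like cells was thus seen in mesothelial-like cells too, though neither list passed camera's test with an estimated correlation.

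Epithelial-like cells of the 3 tumours also differed from each other, which the design does not test. Clusters 1, 7 and 9 held almost only cells of tumour 3 (99.8%, 99.9% and 99.1%), and clusters 16 and 21 mostly cells of tumour 1 (99.6% and 84.5%). Clusters 2, 3, 4, 19 and 25 held cells of both tumours 1 and 2. The gene with the largest ratio between tumours was Xist, the X-inactivation RNA expressed in female cells, at 0.726, 2.13 and 1330 CPM in tumours 1, 2 and 3. The Y-linked genes Ddx3y (56.0, 33.5 and 0.058 CPM) and Eif2s3y (51.4, 39.5 and 0.145 CPM) had the opposite order. By these genes tumour 3 came from a female and tumours 1 and 2 from males, so tumour 3 came from another animal. Sex cannot be told apart from other features of tumour 3. The lactate transporter Slc16a3 (62.9, 39.0 and 2.61 CPM) and the stress-responsive Ankrd1 (112, 70.5 and 5.62 CPM) were lowest in tumour 3. The glucocorticoid-induced Fkbp5 (6.59, 4.26 and 76.8 CPM) and the circadian factor Dbp (9.26, 3.12 and 53.1 CPM) were highest in tumour 3. Ifi202b stood at 3.68, 67.5 and 55.8 CPM, Zg16 at 52.8, 0.297 and 55.7 CPM and the unnamed gene model Gm10709 at 7.18 and 17.4 CPM in tumours 2 and 3, with its highest level in tumour 1. Of the Zg16 UMIs of thinned epithelial-like cells, 95.6% sat in 3 cells, so its values rest on few cells.

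The authors' deposited table holds log2 fold changes and adjusted p-values of 21005 genes for 19 clusters against the other cells, over all tumours. In the authors' deposited table, 4 clusters (1, 3, 5 and 8) had most of their raised markers from the epithelial list, 3 (2, 4 and 11) from the fibroblast list, 2 (12 and 15) from the pericyte or smooth muscle list, and 1 each from the mesothelial (9), acinar (13) and endothelial (18) lists, while 7 had fewer than 3 raised markers of any list. Msi2 was raised at an adjusted p under 0.05 in 0 clusters of the authors' deposited table, with 0.70 in cluster 1 (adjusted p = 0.121 as deposited). Clusters 6 and 10 of the authors' deposited table, which took no class, had raised Pax6 (3.63 and 2.62), Gap43 (2.96 and 3.03), Nefl (1.57 and 3.97), Hmga2 (2.15 and 2.13) and Cdkn2a (1.69 and 1.11) and lowered Epcam (-4.83 and -4.63). Mesothelial cluster 9 of the authors' deposited table had raised Upk3b (8.40) and Cd74 (6.62) and lowered Cdkn2a (-4.37).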

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

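The tests of explanations for the unnamed clusters of tumour 2 and of the Msi2 contrast between classes were chosen after the results they weigh had been seen.

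The 4 unnamed clusters found almost only in tumour 2 held 2621 of its cells, in no comparison of the report. They stood out because tumours 1 and 3 gave 6 and 2 such cells. They had little Epcam (22.6 CPM against 1588 in epithelial-like cells of that tumour) and little Col1a1 (337 against 4485 CPM in fibroblast-like cells), but much vimentin (3077 CPM) and Cdkn2a (1851 CPM, against 869 in epithelial-like and 411 in fibroblast-like cells). The keratins Krt8 and Krt18 lay between those classes, at 412 and 552 CPM against 2029 and 3503 in epithelial-like and 57.9 and 93.3 in fibroblast-like cells. By ratio to the higher of those classes they were led by Grp, a neuropeptide (40.6-fold, 175 CPM), the neurofilament genes Nefm (40.2-fold) and Nefl (28.6-fold), the transcription factor Pax6 (34.1-fold), Lingo2 (30.8-fold) and the growth cone protein Gap43 (26.4-fold). Against epithelial-like cells of tumour 2, the log2 ratio had a median of 2.41 over epithelial-mesenchymal transition genes and 1.42 over G2 and M phase genes (both at percentile 100 of 10000 random lists of like expression) and -5.13 over classical tumour genes (percentile 0). Over fibrillar matrix genes it was 2.14 (percentile 100). Against fibroblast-like cells it was 2.64 over G2 and M phase genes (percentile 100), -2.99 over fibrillar matrix genes (percentile 0) and -0.54 over epithelial-mesenchymal transition genes (percentile 1.08). Of these clusters, cluster 15 (575 cells, median 21034 UMIs against 12067 over all 4) was led by cell cycle genes such as Top2a and Cdk1. The sums were not split by cluster, so its part in the G2 and M phase values is not given. The percentiles describe this 1 tumour, and no test across tumours was made.

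Doublets of epithelial- and fibroblast-like cells would carry epithelial markers, but over the 10 epithelial markers the median level was 2.48% of that in epithelial-like cells. Schwann and endocrine cells would carry their markers, but 0 of 6 and 0 of 8 of these reached 50 CPM. A feature of 1 library or animal stays open, since 99.7% of the cells come from tumour 2 and no second library of it was analysed here. The design names no group that gives a biological explanation, so apart from these cell types none was tested.

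Endothelial-like cells, a class in no comparison, numbered 325 after a sort against CD31, with 218, 18 and 89 in tumours 1, 2 and 3.

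The difference between Msi2-detected and Msi2-undetected cells itself differed between epithelial- and fibroblast-like cells for 25 of 12030 genes (interaction term, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), against 724 at an unadjusted p under 0.05. In the same fit 82 genes passed within epithelial-like and 130 within fibroblast-like cells. Saa3 was at 0.25 in epithelial-like and -1.26 in fibroblast-like cells, C3 at 0.29 and -0.46, Lcn2 at 0.28 and -0.58, Tff2 at -0.18 and -1.38, and Spp1 at 0.03 and 0.71 (log2 fold change, adjusted p of the difference at most 0.00193, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Lcn2 is an epithelial marker and Tff2 a gene of the classical tumour list. In fibroblast-like sums, epithelial markers reached a median of 4.1%, 2.68% and 3.45% of their epithelial-like level in tumours 1, 2 and 3. Whether RNA of epithelial-like cells accounts for the Lcn2 and Tff2 values in fibroblast-like cells was not tested. The largest differences were of Pyy, Ppy, Hbb-bs and Hba-a1, genes of endocrine cells and red blood cells.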

How the results depend on the processing

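Mean share of epithelial-like cells (48.8%) stayed within 1 SD under every alternative run, from 41.7% to 49.3%, and from 44.3% to 55.8% with 1 tumour left out. With variable genes from odd-numbered lines, or with all barcodes except doublets, an epithelial cluster lost its name through the T cell marker Trbc2. In tumour 2 epithelial-like cells then went from 34.9% to 20.8% and 20.4%, and unnamed cells from 48.9% to 63.1% and 61.9%. In tumour 1 unnamed cells went from 9.30% to 0.23% at Leiden resolution 0.5 and 2.15% with doublets kept. They reached 16.8% with odd-numbered lines and 15.04% with all barcodes except doublets. Mesothelial-like cells went from 4.60% and 1.54% of tumours 1 and 2 to 11.8% and 4.97% at resolution 0.5, 8.49% and 2.41% at resolution 2, 8.46% and 2.45% with doublets kept, and 7.61% and 2.44% with at least 1000 genes per cell. With odd-numbered lines no cluster took the endocrine name. Unnamed cells of tumour 3 went from 4.48% to 1.57% at resolution 0.5 and 2.34% with all barcodes except doublets. Pericyte- or smooth muscle-like cells of tumours 2 and 3 went from 2.49% and 4.17% to 4.18% and 6.63% at resolution 0.5. They were at 4.19% and 6.49% with all barcodes except doublets. The fibroblast-like and pericyte- or smooth muscle-like counts of genes kept their size within 1.5 times except for the fit with no replicate block, which gave 3895 genes in place of 6186 and 3010 in place of 4759. With 1 tumour left out these counts ran from 4779 to 5788 and from 3614 to 4705. Named genes of these comparisons kept direction and call in 1727 of 1752 and 1734 of 1790 cases, lost the call in 23 and 49 and gained it in 1 and 7. With no replicate block 13 and 9 of their calls were lost, and 19 and 29 in the Msi2 and mesothelial-like comparisons. Cd74 against fibroblast-like cells turned to -0.54 with doublets kept. With the correlation estimated per list, the lists that passed went from 11 to 0 against fibroblast-like, 13 to 0 against pericyte- or smooth muscle-like, and 2 to 0 in the Msi2 comparison, where 1 passed with no replicate block. The median of p53 targets ran from -0.75 to -0.46 against fibroblast-like cells with 1 tumour left out, and lost its unadjusted call without tumour 2. Against pericyte- or smooth muscle-like cells it ran from -0.31 to -0.18.

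The Msi2 comparison depended on the processing. In place of 49 genes, edgeR called 0 with no replicate block, DESeq2's Wald test 17, and edgeR 309 with no filter on low counts, 29 at Leiden resolution 0.5, 150 with doublets kept, 186 with at least 1000 genes per cell, 90 with at most 10% mitochondrial counts, 27 thinned to 1500 UMIs, 146 without thinning and 5 with matched cluster makeup. With 1 tumour left out the count ran from 4 (without tumour 3) to 59. Named genes kept direction and call in 310 of 485 cases. Without thinning, Scara3 turned to -0.012, Lcn2 to -0.28, Trf to -0.11, Malat1 to -0.063, Anxa10 to 0.037, Tuba1a to 0.10 and Vim to 0.11. With all barcodes except doublets Muc6 turned to 0.075. Detection of Msi2 without thinning follows depth, which parts the arms by construction. In the mesothelial-like comparison, Cd44 turned from -0.24 to 0.62 at resolution 0.5 and to 0.40 at resolution 2. The cause was not tested for the other changes. Thinning to 3000 UMIs limits what the Msi2 comparison can detect.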

Other observations

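The comparison of mesothelial-like with fibroblast-like cells, the tests of Cdkn2a RNA and of other splits of the samples, and, for the genes called by Msi2, the test of a few cells and the bounds for cluster makeup, were chosen after the results had been seen. The draw of Msi2-undetected cells to match the clusters was planned before.

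Mesothelial-like cells had far more MHC class II RNA than fibroblast-like cells: the invariant chain Cd74 was higher by 8.98 ± 0.25 (log2 fold change, SE, n = 3), H2-Aa by 8.12 ± 0.19, H2-Eb1 by 7.10 ± 0.20 and H2-Ab1 by 4.60 ± 0.43, and all 6 tested members were higher. The secretory protease inhibitor Slpi (8.78 ± 0.22), the membrane glycoprotein Gpm6a (8.12 ± 0.28) and the keratin Krt14 (7.98 ± 0.33) were higher as well. Most of these cells were in cluster 22 in tumours 1 and 2 and in cluster 23 in tumour 3 (344 of 353). Cluster 23 was led by Calca, Cd7, Slpi, H2-Aa, H2-Eb1, Cd74, Cxcl13 and Trem2, with 0 mesothelial markers among its 10 leading genes, although all 6 were raised in it. Cd7 (5.77 ± 0.36) and the macrophage receptor gene Csf1r (2.41 ± 0.34) were higher too, while Ptprc had 0 counts in these cells in all 3 tumours. The chemokine Ccl11 (-6.57 ± 0.29), Osr2 (-6.32 ± 0.28), the Wnt antagonist Dkk2 (-5.85 ± 0.23) and the growth factor Igf2 (-5.76 ± 0.25) were lower. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2079 of 10082 genes differed, 1153 higher and 926 lower. The count was 901 without the tumour as a block, 830 without tumour 1 and 1345 without tumour 2. Adjusted p was 5.7e-06 for Cd74 by that edgeR test with Benjamini-Hochberg adjustment, higher in 3 of 3 tumours. MHC class II genes had a median of 5.85 (camera, adjusted p = 6.1e-08, and adjusted p = 0.502 with an estimated correlation). MHC class I genes were higher in 11 of 11 cases (median 1.58, adjusted p = 4.0e-09, and adjusted p = 0.506 with an estimated correlation). Interferon response genes were higher in 15 of 17, 16 when adjusted over the list alone, with Oasl2 at 4.02 ± 0.24 and Gbp2 at 3.69 ± 0.18 (median 1.75, adjusted p = 5.8e-10, and adjusted p = 0.502 with an estimated correlation). Immediate early and heat shock genes were higher in 15 of 18, 17 when adjusted over the list alone, with Atf3 at 3.31 ± 0.19 (median 0.74, adjusted p = 2.4e-07, and adjusted p = 0.502 with an estimated correlation). Fibrillar matrix genes were lower in 20 and higher in 1 of 22 (median -1.84, adjusted p = 6.1e-08, and adjusted p = 0.506 with an estimated correlation), with Tnc at -4.53 ± 0.61 and Postn at -4.31 ± 0.25.

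Among the other unnamed clusters, cluster 13 (7.13%, 3.36% and 0.441% of tumours 1, 2 and 3) was led by Serpinb2, Saa3 and Ccl2, and carried Pdgfra at 78.1 ± 24.2 CPM (SD, n = 3). Cluster 28, with 112 of its 121 cells from tumour 3, was led by the adipocyte genes Cfd, Retn and Adipoq.

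Cdkn2a and Cdkn2b RNA was not limited to epithelial-like cells: Cdkn2a averaged 714 ± 195 CPM there, 364 ± 213 in fibroblast-like, 64.6 ± 32.9 in pericyte- or smooth muscle-like and 67.2 ± 43.5 in mesothelial-like cells (SD, n = 3). Its log2 fold change was -2.42 ± 0.19 in mesothelial-like against fibroblast-like cells (adjusted p = 2.7e-04, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), lower in 3 of 3 tumours. Free RNA of epithelial-like cells would reach each class alike, but the lowest of the 6 ratios of fibroblast-like to pericyte- or smooth muscle-like CPM was 3.41. Epithelial-like cells mixed into fibroblast-like droplets would bring at most 15.4% of either gene, judged from the epithelial markers. Within fibroblast-like cells Cdkn2a ranged from 36.4 CPM in cluster 14 of tumour 1 to 652 CPM in cluster 5 of tumour 3. The design names no group that bears on this pattern, so no biological explanation was tested.

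The 49 genes called between Msi2-detected and Msi2-undetected cells could come from a few cells with very high counts or from a different cluster makeup of the groups. Only 8 of the 49 had 25% or more of their UMIs in 3 cells, which argues against the first for the set while it covers Zg16, Lypd8 and Tff3. With Msi2-undetected cells drawn to match the clusters, a median of 71.6% of the log2 fold change was left over the 46 genes tested in both, 45 with the same sign, and 5 genes were called. That value lies between the bounds of 50% and 80% set for and against cluster makeup, so makeup stays open for these genes. No group of the design gives a biological explanation, so none was tested.

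The 6 sums of each comparison can be split in 10 ways, too few for a share under 0.05. As many genes as in the real split were called by 1 of the 10 splits against fibroblast-like cells (6186, highest other 0), by 1 against pericyte- or smooth muscle-like cells (4759, highest other 0), by 1 between mesothelial- and fibroblast-like cells (2079, highest other 0) and by 3 in the Msi2 comparison (49, highest other 53). In the other splits between classes, the class difference itself enters the residual spread. Their 0 calls therefore do not show how many genes chance would call. In the Msi2 comparison both other splits with 53 genes left 2 of the 3 pairs whole. With the tumour as a block, a whole pair adds nothing to the contrast. Both splits therefore made the same comparison, Msi2-detected against Msi2-undetected cells of 1 tumour, and do not show what chance would call. Among the splits that part all 3 pairs, as the real one does, the highest other was 11.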
